A study of Homo sapiens with 8 samples.

How the data were processed

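RNA-seq was made from AGS and SNU-1 cells, untreated or treated with palbociclib for 5 days, in 8 libraries, 2 per group. Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were prepared with a SMARTer mRNA-seq kit. The values are FPKM per gene and library, per the file headers, as the authors deposited them, written with at most 2 decimals. The genome build named in the submitters' processing notes is mm10, a mouse build, although the cells and the gene symbols are human, so no coordinates are given. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. How fragments shared between near-identical genes were counted is therefore open, and values of keratin, MHC class I, histone, ribosomal protein, chemokine and small RNA copies are uncertain in that respect.

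The table held 40189 named genes and 1 entry without a gene name, which was left out (at most 0.000726% of a library's FPKM). Gene symbols were matched to GENCODE release 29 for length and GC content (91.1% of symbols, 95.8% of the tested genes) and to the RefSeq table of the human assembly GRCh38.p14 for biotypes. FPKM keeps no counts, but the low values of genes shorter than 400 nucleotides fall in steps of a single fragment, from which the depth was estimated. The estimates were 19600000, 19100000, 17800000 and 19600000 fragments for AGS control 1, control 2, palbociclib 1 and palbociclib 2, and 17400000, 15300000, 17000000 and 18100000 for the SNU-1 libraries in the same order. Of the lowest short-gene values, those of a few fragments, 95.8% to 99.3% per library lay within 0.1 of a whole number of fragments. The size of the step was itself accepted by this share, so the share is no separate check of the depth. Rounding hides the steps in longer genes, so no count model was run.

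Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a group-means model over all 8 libraries, the mean-variance trend in the moderated test, 2-sided p-values and Benjamini-Hochberg adjustment at 0.05. All 4 groups share the estimate of spread because 2 libraries per group leave 4 residual degrees of freedom. A gene was tested where FPKM was at least 1 in at least 2 libraries, which left 12983 genes. The 4 contrasts were palbociclib against control in each line, the difference between those effects, and AGS control against SNU-1 control. Agreement between the lines was measured by overlap of calls against a hypergeometric distribution and by correlation across genes.

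Gene lists, 29 in all, cover DNA replication, mitosis, the CDK4/6 and RB pathway, homologous recombination, p53 targets, senescence-associated secretory factors, the interferon response, MHC class I, checkpoint ligands, the lysosome, cholesterol synthesis, oxidative phosphorylation, glycolysis, the ATF4 response, ribosome biogenesis, ERK feedback, Wnt targets, apoptosis, gastric and intestinal epithelium, epithelial junctions, mesenchymal genes, xenobiotic metabolism, fibroblast, leukocyte and endothelial markers, immediate early genes, ribosomal proteins and mitochondrially encoded genes. The 25 lists with at least 5 tested members were tested with limma's camera at the preset correlation of 0.01, with camera at an estimated correlation, and with fry. Fry asks whether a list's own fold changes depart from 0, without comparing them with other genes. List medians are given minus the median of all genes tested. This was chosen after the data were seen, because the median of all genes in SNU-1 lay more than 0.1 from 0 on the log2 scale. Positive and negative members are counted on the fold changes as fitted.

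The text names, for each treatment contrast, the 8 genes of largest rise and the 8 of largest fall past the threshold whose treated libraries lie on the same side of both controls, 6 and 6 for the controls, and for the difference between the lines the 3 of smallest p, since none passed. Symbols that are clone or locus names, microRNA, small nucleolar RNA or antisense names were skipped. From each list up to 4 members of smallest adjusted p, and 13 cell cycle regulators, could be named. Genes of the Y chromosome and XIST were left out of the named genes. Not every gene this rule allowed is reported here, and 1 was left out for a reason other than its values. The design, this rule and the lists were fixed before the data were examined.

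Chosen before the data were examined were a pseudocount of 0.1, no filter, a filter at FPKM 5, median-of-ratios size factors, TPM, quantile normalization, each line fitted alone, no mean-variance trend, the replicate number as a block, each library left out in turn, a fold change of at least 2, and the other list tests. Chosen after seeing the data were a fit of protein-coding genes, the naming rule applied without SNU-1 palbociclib replicate 2, a fit without both treated SNU-1 libraries, removal of the GC trend in the 12435 genes with a known GC content, and a fit of those genes with the trend left in. The removal subtracts, in each library and each of 20 GC bins, the median deviation from the control mean of the line. It recenters the controls too and charges no degrees of freedom, and the SD between SNU-1 controls went from 0.359 to 0.302. It would also take out a drug effect that follows GC content, so counts after it are not a neutral check.

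The fit was tested on simulated data with known fold changes in AGS over 12983 genes. Changes were planted only in genes with an AGS control mean above 2 on the log2(FPKM + 1) scale. Each gene had the same noise in every group. The recovery therefore does not cover weakly expressed genes or a spread that sits in 1 library. With the spread of all 8 libraries it recovered 53.2% of 111 genes changed by 2 on the log2 scale and 2.25% of 89 changed by 1, with 2 false calls. With the spread found without SNU-1 palbociclib replicate 2 it recovered 100% and 79% of 100 genes each, with 20 false calls. Depth and step estimates and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.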

Results

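RNA was sequenced from AGS and SNU-1, both established human gastric cancer cell lines, with and without 5 days of palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6. Each of the 4 groups, AGS control, AGS palbociclib, SNU-1 control and SNU-1 palbociclib, held 2 libraries. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The drug concentration is not given in the sources used here. Values were the authors' FPKM, fragments scaled to transcript length and library total, for 40189 named genes. The single-fragment steps of short genes put the depth at 17800000 to 19600000 fragments per AGS library and 15300000 to 18100000 per SNU-1 library. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes, and 12983 genes were tested.

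SNU-1 palbociclib replicate 2 stood apart from the other 7 libraries. It had 8545 genes at 1 FPKM or more against 10896 to 11543 in the others, and ribosomal protein genes held 15.3% of its FPKM against 4.43% to 9.34%. Its Pearson correlation with its replicate was 0.867 across genes, while the other replicate pairs reached 0.978 to 0.990. Relative to the controls of the same line, genes of low GC content lay lower than genes of high GC content in all 4 treated libraries. GC content explained 18.8% and 36.5% of the variance of this deviation across genes in AGS replicates 1 and 2, and 10.7% and 51.3% in SNU-1 replicates 1 and 2. A GC trend also separated the 2 untreated SNU-1 libraries, where the median difference of replicate 2 from replicate 1 ran from -0.48 in the bin of lowest GC content to 0.18 in the bin of highest, so it is not tied to treatment alone. The median of all genes was -0.02 for palbociclib in AGS and -0.24 in SNU-1 (-0.06 without SNU-1 palbociclib replicate 2), so gene list values are given relative to it.

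**Figure D1:**
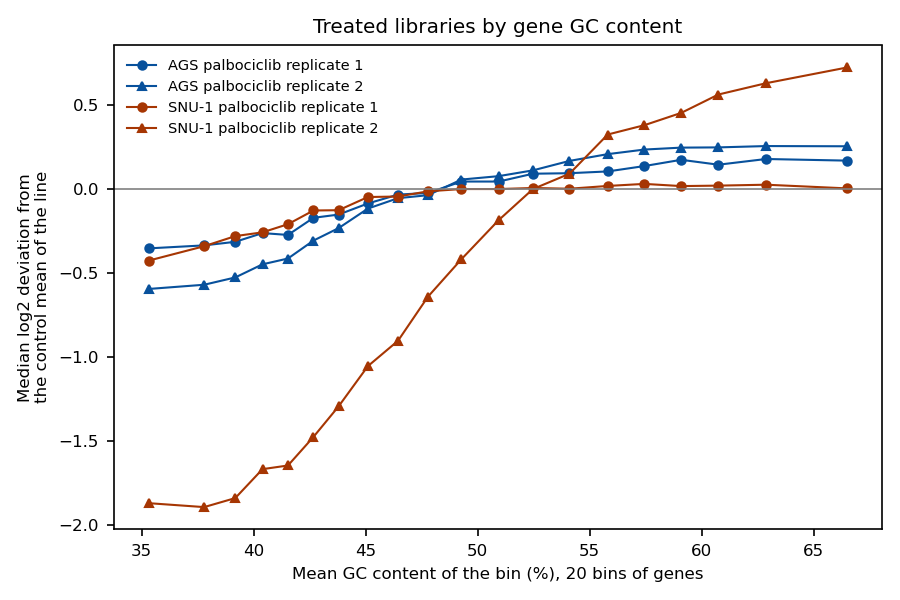
Median deviation of each palbociclib library from the control mean of its line (y axis, log2) over 20 bins of genes ordered by mean GC content (x axis, percent). In SNU-1 palbociclib replicate 2 the line runs from -1.87 in the bin of lowest GC content to 0.72 in the bin of highest, and in AGS palbociclib replicate 2 from -0.59 to 0.25.

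The first comparison asked which genes differed between AGS cells treated with palbociclib and untreated AGS cells. Treated cells had more mRNA of MSMB and of interferon-induced genes such as CXCL10 and OASL, and less of CXCL8, the neutrophil chemokine interleukin 8, and of FGB, the fibrinogen beta chain. MSMB, a secreted microseminoprotein, rose from 2.26 and 6.11 FPKM to 53.38 and 41.03 FPKM, a log2 fold change of 3.31 (SE 0.37, limma, Benjamini-Hochberg adjusted p = 0.0315). It was 0 FPKM in every SNU-1 library, and in a fit of AGS alone it narrowly missed the threshold (limma adjusted p = 0.0504). CXCL10, an interferon-induced chemokine, rose from 4.63 ± 1.14 to 25.4 ± 6.13 FPKM (SD, n = 2 libraries), and OASL, an interferon-induced antiviral gene, from 6.43 ± 2.24 to 33.9 ± 1.48 FPKM (SD, n = 2). CXCL8 fell from 16.0 ± 0.21 to 3.54 ± 0.79 FPKM (SD, n = 2), a log2 fold change of -1.92 (SE 0.19, limma adjusted p = 0.0287).

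In the fit of all 8 libraries, limma called 29 genes higher and 4 lower in treated AGS cells at an adjusted p under 0.05. Beside MSMB the largest rises were those of SPRR1A, a cornified envelope protein of squamous epithelia (2.50), IGFBP6, a binding protein of insulin-like growth factors (2.46), SERPINB2, plasminogen activator inhibitor 2 (2.40), OASL (2.27), RAET1L, a ligand of the NKG2D receptor (2.24), CXCL10 (2.23) and APOL1, apolipoprotein L1 (2.22). FGB fell by 1.87. The other called decreases, SNORD58 and MIR4427, lie outside the naming rule and were named after their values were seen. Both are listed at 0 in the treated AGS libraries, and the fragments of such short genes cannot be assigned with certainty. Of the 33 called genes, 32 had a mean FPKM under 1 in both SNU-1 groups, compared with 1539 of the 12983 genes tested. The spread of each gene is pooled over all 4 groups, so genes near 0 in SNU-1 take on little of the spread between its treated libraries. The 33 genes are therefore not a neutral sample of the AGS response.

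The number of calls depended on the libraries in the fit. With SNU-1 palbociclib replicate 2 left out, limma called 615 genes higher and 636 lower in treated AGS cells, the 33 genes above among them, and 118 and 199 of these changed at least 2-fold. With SNU-1 palbociclib replicate 1 left out it called 629 and 636, and with AGS palbociclib replicate 2 left out 4 and 0. Leaving out AGS control replicate 1 or 2, AGS palbociclib replicate 1, or SNU-1 control replicate 1 or 2 left 0 genes called, with 478 to 774 at an unadjusted p under 0.05, where the fit of all libraries had 1008. Rescaling to TPM gave 3 higher and 2 lower, and removing the GC trend from each library 4 higher and 0 lower. The latter covers the 12435 genes with a known GC content, which gave 28 higher and 3 lower with the trend left in.

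Cell cycle genes were lower in treated AGS cells. All 38 members of the mitosis list had a negative fold change, with a median of -1.04 relative to all genes (limma camera, adjusted p = 6.69e-19). The median was -0.63 over the 44 genes of DNA replication and S phase, 42 of them negative (adjusted p = 5.14e-13), and -0.90 over the 20 genes of homologous recombination and the replication checkpoint, 19 of them negative (adjusted p = 2.04e-11). With an estimated correlation between genes each of these lists had an adjusted p = 0.230. By fry the adjusted p was 0.0456 for mitosis and for replication, and 0.0826 for recombination. In the fit of all 8 libraries 0 members of the 3 lists passed the test for single genes, over all genes or adjusted over the list alone. With SNU-1 palbociclib replicate 2 left out, limma called 25 mitosis, 19 replication and 12 recombination genes lower and 0 of their members higher. TOP2A, the DNA topoisomerase of dividing cells, then fell from 82.5 ± 4.74 to 21.3 ± 1.41 FPKM (SD, n = 2; -1.90, SE 0.20, limma adjusted p = 0.0125) and the proliferation marker MKI67 from 44.4 ± 1.92 to 12.5 ± 0.70 FPKM (SD, n = 2; -1.75, SE 0.19, limma adjusted p = 0.0129). Among the other decreases of that fit were HMGB2, a chromatin protein (-1.76), and NUF2, a kinetochore protein (-1.76). With the GC trend removed the medians were -0.85 for mitosis, -0.67 for replication and -0.68 for recombination.

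Interferon response and lysosome genes were higher in treated AGS cells. The type I interferon list had a relative median of 0.53, with 23 of 26 tested members positive (camera adjusted p = 5.66e-10; adjusted p = 0.253 with an estimated correlation). By fry its adjusted p was 0.0784. OASL passed over all genes and 3 members rose when adjusted over the list alone. In the fit without SNU-1 palbociclib replicate 2, limma called 6 of the 26 higher, among them the ubiquitin-like ISG15 (1.53, SE 0.20, adjusted p = 0.0180) and the antiviral RSAD2 (1.48, adjusted p = 0.0223). With the GC trend removed the interferon median was 0.87 (camera adjusted p = 2.52e-09). The lysosome list had a relative median of 0.61, with 30 of 31 positive (camera adjusted p = 7.04e-11; adjusted p = 0.217 with an estimated correlation), and 0 members passed in the fit of all 8 libraries. As a list it passed fry (adjusted p = 0.0312). When that library was left out 16 rose, among them PSAP, the precursor of the saposins, from 291 ± 30.1 to 582 ± 19.0 FPKM (SD, n = 2).

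Smaller differences had camera adjusted p-values under 0.05 in AGS and did not keep them with an estimated correlation. By fry, checkpoint ligands, epithelial junction genes and immediate early genes each had an adjusted p = 0.0456. MHC class I (0.111), xenobiotic metabolism (0.0874) and mitochondrially encoded genes (0.164) did not pass fry. MHC class I genes had a relative median of 0.41 (adjusted p = 0.00553; 0.287 as an adjusted p with an estimated correlation) and immune checkpoint ligands 0.47 (0.00810; 0.230). Xenobiotic metabolism genes had 0.35 (0.00700; 0.287), epithelial junction and keratin genes 0.36 (0.0148; 0.230), which became 0.20 (0.0632) with the GC trend removed, mitochondrially encoded genes 0.25 (0.00356; 0.335), and immediate early and heat shock genes -0.40 (0.0356; 0.230). With the GC trend removed mitochondrially encoded genes had 0.43 (camera adjusted p = 0.00924), while their value changed sign after quantile normalization. Oxidative phosphorylation then had 0.24 (0.0625) and glycolysis 0.016 (0.413) with the GC trend removed. The epithelial and immediate early lists lost the camera call without SNU-1 palbociclib replicate 2 (adjusted p = 0.0546 and 0.0559, with unchanged medians), while oxidative phosphorylation and glycolysis gained it (adjusted p = 0.00665 and 0.0378; 0.605 and 0.371 as adjusted p-values with an estimated correlation). In that fit the aryl hydrocarbon receptor target CYP1A1 rose by 1.41 (limma adjusted p = 0.0454) and MYC by 0.59 (adjusted p = 0.0408), and the transcription factor EGR1 had a fold change of -1.21 (adjusted p = 0.0348).

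The list of the CDK4/6 and RB pathway had a relative median of -0.08 in AGS, with 10 of 23 tested members positive (camera adjusted p = 0.282). In the fit without SNU-1 palbociclib replicate 2, CCND1, the cyclin D1 partner of CDK4 and CDK6, was higher at 261 ± 5.18 against 178 ± 3.01 FPKM (SD, n = 2; 0.55, limma adjusted p = 0.0298), and the repressors E2F7 and E2F8 were lower (-1.23 and -1.21, both adjusted p = 0.0130). The values of CDK6 (-0.61, adjusted p = 0.0563), CCND3 (0.62, adjusted p = 0.0524), CCNE1 (0.47, adjusted p = 0.0851), CCNE2 (-0.77, adjusted p = 0.0563), RB1 (-0.57, adjusted p = 0.120), E2F1 (-0.21, adjusted p = 0.543), CDKN1A (0.13, adjusted p = 0.828), CDKN2A (0.51, adjusted p = 0.237) and CDK4 (-0.02, adjusted p = 0.966) did not pass limma's test in that fit. CCND2 was below the filter. The remaining tested lists missed the camera threshold in AGS. Their relative medians were -0.13 for p53 targets, 0.19 for senescence-associated secretory factors, 0.05 for cholesterol synthesis, 0.19 for oxidative phosphorylation, 0.19 for glycolysis, -0.37 for the ATF4 response, -0.04 for ribosome biogenesis, -0.05 for ERK feedback, -0.30 for Wnt targets, 0.04 for apoptosis regulators, 0.36 for intestinal epithelium, 0.27 for mesenchymal genes and 0.08 for ribosomal proteins. With the GC trend removed, the ATF4 response (-0.59, camera adjusted p = 0.0276) and Wnt targets (-0.42, adjusted p = 0.0266) passed camera at the preset correlation, the only one tried there. Among the secretory factors IGFBP6 rose and CXCL8 fell over all genes, and 2 rose and 5 fell when adjusted over the list alone.

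**Figure D2:**
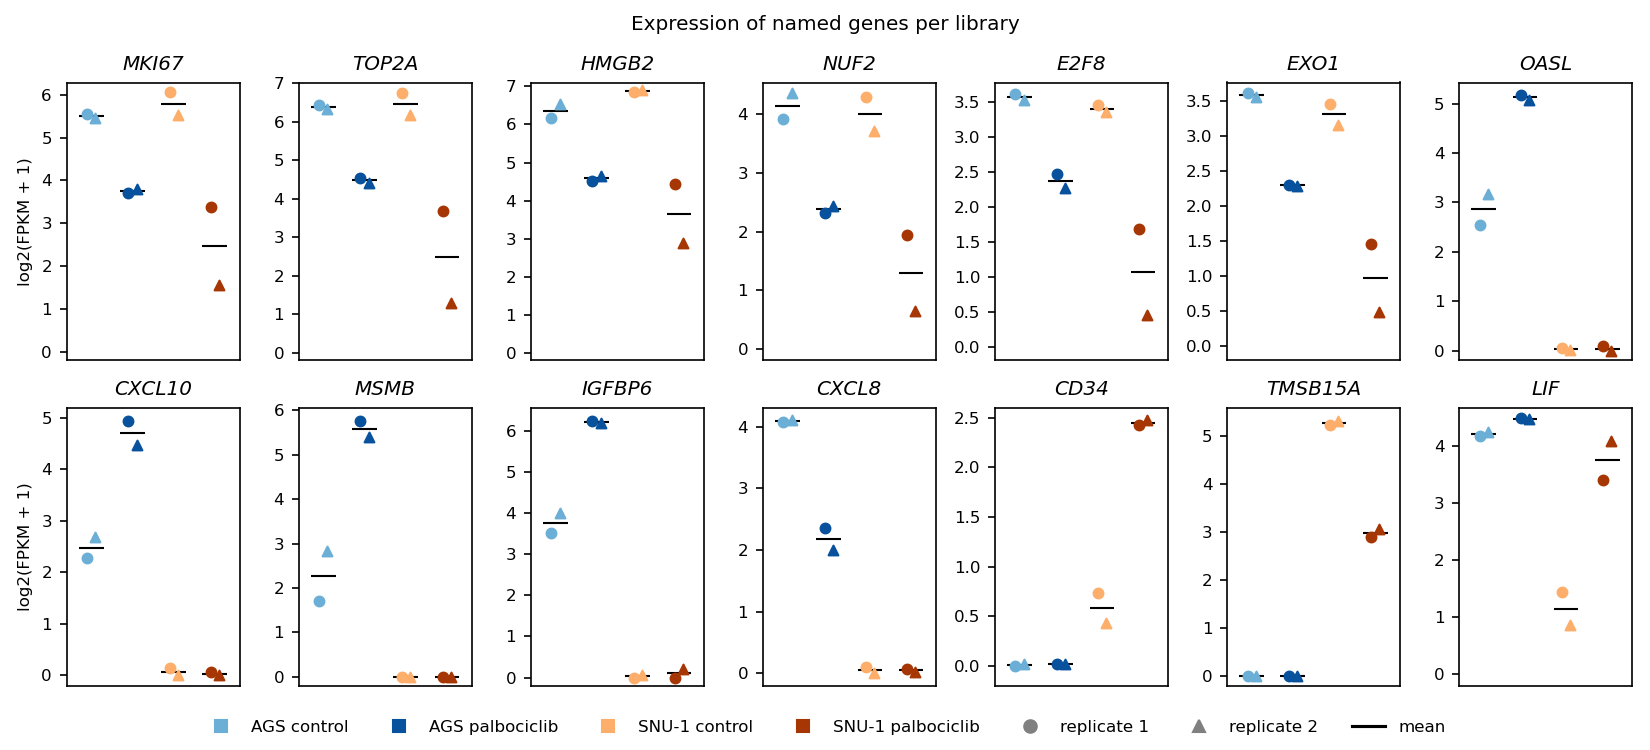
Expression of 14 named genes in each of the 8 libraries (y axis, log2 of FPKM + 1), with circles for replicate 1, triangles for replicate 2 and a bar at each group mean. MKI67 and TOP2A lie lower in all treated libraries of both lines, CXCL10 and OASL lie higher in treated than in control AGS libraries and near 0 in SNU-1, and CD34 was 4.36 and 4.56 FPKM in treated SNU-1 libraries against 0.66 and 0.35 in their controls.

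The second comparison asked the same of SNU-1. CD34, a surface sialomucin best known from blood progenitors and endothelium, rose from 0.51 ± 0.22 to 4.46 ± 0.14 FPKM (SD, n = 2; 1.87, SE 0.15, limma adjusted p = 0.0230). TMSB15A, a thymosin beta protein that binds actin, fell from 37.7 ± 1.78 to 6.90 ± 0.59 FPKM (SD, n = 2; -2.29, SE 0.19, limma adjusted p = 0.0230). It was not called in the fit of protein-coding genes or with the filter at FPKM 5. Cell cycle genes were lower as a group, and lysosome, MHC class I and ribosomal protein genes higher, by camera at the preset correlation and not at an estimated one (adjusted p = 0.298 to 0.434). Without SNU-1 palbociclib replicate 2 the relative medians of the last 3 lists fell from 0.89, 0.74 and 1.12 to 0.47, 0.40 and 0.45.

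In the fit of all 8 libraries limma called 1 gene higher and 9 lower in treated SNU-1 cells. Of these 10 genes, 8 are short non-coding genes whose values are 0 in both treated libraries. They are RNU6-1257P (3.13 and 2.96 FPKM in the controls), RNA5SP418, RNA5SP423, RNU6-1051P, RNU7-151P and RNU6-647P, copies of small nuclear and 5S ribosomal RNA genes, and, named after their values were seen, MIR5685 and SNORD58. The 7 of them with an annotated length of 53 to 117 nucleotides rest on a median of 2.49 fragments per control library, and fragments of such copies cannot be assigned with certainty.

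With SNU-1 palbociclib replicate 2 left out, limma called 60 genes higher and 280 lower in SNU-1, all 10 genes above among them. That fit holds a single treated SNU-1 library, which is assumed to vary like the other groups. Its largest rises were those of LIF, an interleukin 6 family cytokine (2.26, SE 0.24, adjusted p = 0.0137), S100A3, a calcium-binding protein (2.14), CD34 (1.84), ECM1, an extracellular matrix protein (1.81), the interferon-induced IFIT1 (1.73, but 1.05 with all 8 libraries), the lysosomal lipase LIPA (1.66), PLA2G4C, a phospholipase (1.59), and the chemokine CCL17 (1.56). Its largest decreases were RNU6-415P, TOP2A (-2.78), RNA5SP323, the kinetochore protein CENPF (-2.48), RPS29P16 (-2.47), the mitotic motor KIF11 (-2.45), HMGB2 (-2.44) and the condensin subunit NCAPG (-2.42). Without replicate 1 instead, which leaves only the library that stood apart, 2716 genes were called higher and 6051 lower. Leaving out any AGS library or SNU-1 control replicate 1 left 0 called (805 to 1788 at an unadjusted p under 0.05, against 3027 with all libraries), leaving out SNU-1 control replicate 2 left 0 higher and 1 lower, and a limma fit of SNU-1 alone called 0 (855 at an unadjusted p under 0.05). Median-of-ratios size factors gave 1 higher and 3 lower, TPM 0 higher and 10 lower, and removal of the GC trend 80 higher and 248 lower over the 12435 genes with a known GC content, 4 of the 10 genes above among them, where 1 higher and 7 lower were called with the trend left in.

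The mitosis list had a relative median of -2.10 in SNU-1, with all 38 members negative (camera adjusted p = 1.66e-18; adjusted p = 0.298 with an estimated correlation). The DNA replication list had -1.08, with 43 of 44 negative (adjusted p = 7.76e-13; 0.372 as an adjusted p with an estimated correlation), and the recombination list -1.41, with all 20 negative (3.08e-09; 0.434). By fry the adjusted p was 0.00721 for mitosis and for replication, and 0.0188 for recombination. No member passed over all genes in the fit of all 8 libraries, SNU-1 palbociclib replicate 2 included, while 37 mitosis, 33 replication and 17 recombination genes fell and 1 replication gene rose when adjusted over the list alone. After that library was left out, limma called 34, 26 and 11 of them lower over all genes, and the relative medians were -1.67, -1.10 and -1.16. In the fit without SNU-1 palbociclib replicate 2, MKI67 had a fold change of -2.40 (SE 0.23, adjusted p = 0.0122), the ribonucleotide reductase subunit RRM2 -2.17 (adjusted p = 0.0141), the exonuclease EXO1 -1.84 (adjusted p = 0.0122) and E2F1 -1.48 (adjusted p = 0.0411). The E2F1 decrease rests on replicate 1, since E2F1 was 25.6 ± 3.28 FPKM in controls (SD, n = 2) and 8.47 and 21.8 FPKM in treated replicates 1 and 2, and it was -0.85 with all 8 libraries (adjusted p = 0.243). With the GC trend removed, 28 mitosis, 19 replication and 9 recombination genes were called lower, with relative medians of -1.53, -1.13 and -0.83.

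Other lists had camera adjusted p-values under 0.05 in SNU-1, and none of them with an estimated correlation. By fry lysosome genes passed (adjusted p = 0.0188). MHC class I (0.156), ribosomal protein (0.172), oxidative phosphorylation (0.259) and glycolysis genes (0.172) did not pass fry. Lysosome genes had a relative median of 0.89 (adjusted p = 4.07e-07; 0.298 as an adjusted p with an estimated correlation), MHC class I genes 0.74 (0.000883; 0.434), ribosomal protein genes 1.12 (1.23e-16; 0.434), oxidative phosphorylation 0.69 (1.32e-05; 0.434) and glycolysis 0.71 (0.000530; 0.434). SNU-1 palbociclib replicate 2, the library with the highest ribosomal protein share, moved with these lists. Without it the medians of the last 2 were 0.17 and 0.16. PSAP in that fit had a fold change of 1.20 (limma adjusted p = 0.0232). The CDK4/6 and RB pathway (-0.38), p53 targets (0.21) and the interferon response (0.11) passed camera in that fit (adjusted p = 0.00451, 0.00689 and 0.0196; 0.324, 0.788 and 0.830 as adjusted p-values with an estimated correlation). With the GC trend removed, the lysosome (0.63), MHC class I (0.68), ribosomal protein (1.03), oxidative phosphorylation (0.61) and glycolysis (0.43) lists still passed camera, with larger medians than without that library. At the preset correlation camera then also passed the CDK4/6 and RB pathway (-0.50, adjusted p = 0.00242), the interferon response (0.49, adjusted p = 0.0342), cholesterol synthesis (0.25) and mitochondrially encoded genes (0.46, both adjusted p = 0.0229). The remaining tested lists did not pass camera in the fit of all 8 libraries. There their relative medians were -0.58 for the CDK4/6 and RB pathway (19 of 23 negative, camera adjusted p = 0.0770, fry adjusted p = 0.0188), 0.34 for p53 targets and 0.24 for the interferon response. As fitted, before the median of all genes (-0.24) was subtracted, the last 2 were 0.10 and 0.0039. The others, with the value without SNU-1 palbociclib replicate 2 in parentheses, were 0.24 (0.054) for secretory factors, 0.36 (0.13) for checkpoint ligands, 0.47 (0.045) for cholesterol synthesis, 0.16 (-0.32) for the ATF4 response, 0.0046 (0.052) for ribosome biogenesis, 0.19 (0.14) for ERK feedback, 0.22 (0.030) for Wnt targets, -0.21 (-0.039) for apoptosis regulators, 0.21 (0.026) for intestinal epithelium, 0.18 (0.037) for epithelial junctions, 0.24 (0.074) for mesenchymal genes, 0.24 (0.054) for xenobiotic metabolism, 0.26 (-0.12) for immediate early genes and 0.0014 (-0.018) for mitochondrially encoded genes. As fitted with all 8 libraries, most members were negative for Wnt targets (median -0.021), ERK feedback (-0.053) and intestinal epithelium (-0.031). So were those of epithelial junctions (-0.058) and the ATF4 response (-0.079). Secretory factors (0.0048), mesenchymal genes (0.0068) and xenobiotic metabolism (-0.00062) lay near 0. Checkpoint ligands (0.12), cholesterol synthesis (0.23) and immediate early genes (0.022) were positive. CDKN1A was 59.9 ± 29.1 FPKM in controls and 129 ± 42.4 in treated cells (SD, n = 2), which did not pass the test (adjusted p = 0.210).

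**Figure D3:**
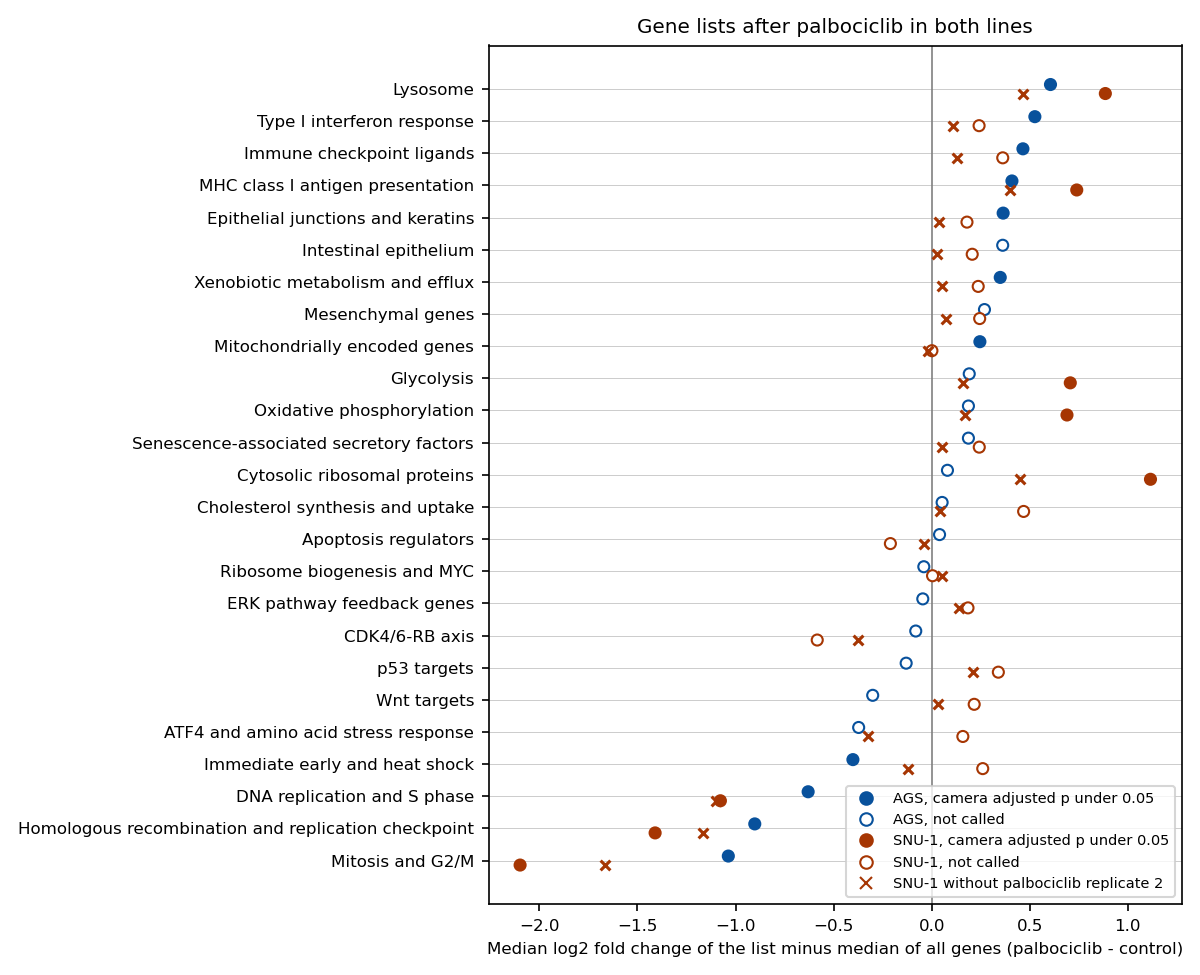
Median log2 fold change of each tested gene list minus the median of all genes (x axis) after palbociclib in AGS (blue) and SNU-1 (red), filled where the camera adjusted p was under 0.05, with crosses for SNU-1 without palbociclib replicate 2. The mitosis list lies at -1.04 in AGS and -2.10 in SNU-1, or -1.67 without that library, and the lysosome list at 0.61 and 0.89, or 0.47.

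The next comparison asked whether the lines responded alike. Across the 12983 genes the AGS and SNU-1 fold changes had a Pearson correlation of 0.68 (Spearman 0.70). It was 0.54 with SNU-1 palbociclib replicate 1 alone, 0.66 with replicate 2 alone and 0.52 after removal of the GC trend, and genes are not independent replicates. The lines have separate controls. Their calls come from a fit that shares each gene's estimate of spread, and treated libraries of both lines show the GC trend. Call lists of the lines are therefore not independent. The hypergeometric p-values below cannot tell a shared drug response from these shared features. In the fit of all 8 libraries SNORD58 was the only gene called lower in both lines, and 0 were called higher in both. With SNU-1 palbociclib replicate 2 left out, 147 genes were called lower in both lines, where independent lists would share 13.7 (exact hypergeometric p = 2.58e-120). TOP2A, HMGB2, NUF2, MKI67 and KIF11 are among them. In that fit 20 genes were called higher in both lines against 2.84 (exact hypergeometric p = 1.69e-12), PSAP and IFIT1 among them, and 1 gene was called in opposite directions. The SNU-1 rise of IFIT1 rests on palbociclib replicate 1 (34.8 FPKM), as replicate 2 had 12.9 FPKM and the controls 12.2 and 7.85 FPKM.

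The test of the difference itself, the AGS effect minus the SNU-1 effect, called 0 genes in either direction with limma (729 at an unadjusted p under 0.05), and 0 without SNU-1 palbociclib replicate 2 (1394). With SNU-1 palbociclib replicate 1 left out, 5409 genes were called higher and 1532 lower in this contrast. The genes of smallest p were RNU6-1257P, SPRR1A and RNA5SP440, none past the test (limma adjusted p = 0.0790 for each). RNA5SP440 is listed at 0 in 6 of the 8 libraries. As groups, 14 lists differed by camera and 0 of them with an estimated correlation (adjusted p = 0.461 to 0.504) or by fry (adjusted p = 0.158 to 0.817). The mitosis list was 0.91 higher in this difference, with 37 of 38 positive (camera adjusted p = 9.12e-10), since its decrease was larger in SNU-1, and the ribosomal protein list -1.09, with 45 of 47 negative (adjusted p = 2.47e-21). These values were 0.73 and -0.36 without SNU-1 palbociclib replicate 2.

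The last comparison set the untreated lines side by side as background. Line and any difference in handling cannot be separated in it. Control AGS cells expressed epithelial genes that were near 0 in SNU-1. KRT18 and KRT8, the keratins of simple epithelia, were 422 ± 59.1 and 383 ± 74.1 FPKM in AGS and 0.43 ± 0.05 and 0.36 ± 0.06 in SNU-1 (SD, n = 2), log2 differences of 8.20 and 8.13. The phospholipase PLA2G2A (7.99), lysozyme LYZ (7.96), cathepsin E CTSE (7.75) and the cystatin CST1 (7.63) followed. SNU-1 had more of the growth factor BMP10 (-7.80), the peptide hormone cholecystokinin CCK (-7.26), SOSTDC1, a secreted BMP antagonist (-6.87), the cancer-testis gene SSX1 (-6.48), NXF3 (-6.32) and thrombomodulin THBD (-6.30). All 12 had a limma adjusted p of 0.000737 or less, and CDK6 was higher in AGS, at 47.8 ± 2.83 FPKM against 0.15 ± 0.11 (SD, n = 2; 5.41, limma adjusted p = 2.28e-05).

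Limma called 1861 genes higher and 1874 lower in control AGS than in control SNU-1 cells. Epithelial junction and keratin genes had a relative median of 5.27, 15 of 16 called higher (camera adjusted p = 1.59e-13), and this list also passed with an estimated correlation (adjusted p = 0.0492), but not without SNU-1 palbociclib replicate 2 (adjusted p = 0.205, with the same median). The other called lists did not pass with an estimated correlation in either fit. They were intestinal epithelium (4.20; adjusted p with an estimated correlation 0.117), Wnt targets (3.75; 0.113), secretory factors (3.72; 0.117), xenobiotic metabolism (1.90; 0.429), the interferon response (1.52; 0.438), mitochondrially encoded genes (0.73; 0.471), immediate early genes (0.67; 0.224), DNA replication (-0.48; 0.625) and ribosomal proteins (-0.55; 0.885). With all 8 libraries these lists had fry adjusted p-values of 0.0269 or less, except ribosomal proteins (0.184). Most markers of other cell types were below the filter, with 2 of 10 fibroblast, 1 of 12 leukocyte and 2 of 8 endothelial genes tested, and 4 of 19 gastric epithelium genes. The leukocyte marker is LYZ, which gastric glands also express. Too few for a list test, these had relative medians in the treated AGS cells of -0.30, 0.61, 0.19 and -0.10, and in the treated SNU-1 cells of -0.38, 0.14, 0.44 and 0.35, or 0.033, -0.042, -0.16 and 0.11 without SNU-1 palbociclib replicate 2. Without AGS control replicate 1 or 2, or SNU-1 control replicate 1 or 2, 999, 1027, 1067 and 1020 genes were called lower in AGS, and without SNU-1 palbociclib replicate 1 or 2 the calls were 3155 higher and 4216 lower, and 3152 and 4211.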

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

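The tests of depth, of a stronger response, of fragment numbers on short genes and of expression in SNU-1 were chosen only after the results they concern were seen, and the test of length and GC content was set before.

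Of the 25 tested gene lists, 14 differed between the lines in their response to palbociclib by limma's camera, in the AGS effect minus the SNU-1 effect relative to all genes. Cell cycle lists were higher in this difference, with 0.91 for mitosis (adjusted p = 9.12e-10), 0.47 for DNA replication (4.06e-05) and 0.36 for homologous recombination (0.00457), as were the interferon response with 0.27 (0.00491) and mitochondrially encoded genes with 0.11 (0.0115). The others were lower, with -1.09 for ribosomal proteins (2.47e-21), -0.30 for p53 targets (0.00806), -0.52 for secretory factors (0.00302), -0.37 for cholesterol synthesis (0.0470), -0.48 for oxidative phosphorylation (0.00119), -0.60 for glycolysis (0.0115), -0.71 for the ATF4 response (0.00806), -0.31 for ERK feedback genes (0.00806) and -0.29 for immediate early genes (0.0155). With an estimated correlation the adjusted p was 0.504 for the ATF4 response and 0.461 for each of the other 13, and by fry it was 0.158 to 0.817. With the GC trend removed the camera call was lost for mitochondrially encoded genes (-0.11), immediate early genes (0.022) and secretory factors (-0.35). It was also lost for the ATF4 response (-0.56), cholesterol synthesis (-0.23) and glycolysis (-0.37). Camera adjusted p-values of these lost calls were 0.0535 to 0.694. Without SNU-1 palbociclib replicate 2 the camera call was lost for secretory factors (-0.11), cholesterol synthesis (0.060), oxidative phosphorylation (0.032), glycolysis (0.026), the ATF4 response (-0.21) and immediate early genes (-0.36), and gained for the CDK4/6 and RB pathway (0.32, adjusted p = 0.0174; 0.669 with an estimated correlation), which also passed with the GC trend removed (0.47, adjusted p = 0.00719). As fitted, before the median of all genes (0.29) was subtracted, cholesterol synthesis had a median of -0.079 and a mean of 0.014, and immediate early genes a median of 0.0060 and a mean of -0.024, so for each list 1 of the 2 values was opposite in sign to the test. P53 targets (-0.0011, 12 of 25 positive) and ERK feedback genes (-0.018, 8 of 16 positive) lay near 0 as fitted. Secretory factors were at -0.22 with 8 of 16 positive. Ribosomal proteins (-0.79), the ATF4 response (-0.42), glycolysis (-0.30) and oxidative phosphorylation (-0.18) were negative as fitted.

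SNU-1 palbociclib replicate 2 differed from its replicate with an SD of 1.03 over genes on the log2 scale, against 0.258 to 0.359 in the other replicate pairs. A shallower library is argued against, since its depth was 1.01 times the mean of the other 7. Length and GC content explained 56.4% of the variance of the difference, which is consistent with a GC bias of that library, although removing the GC trend left an SD of 0.706 against 0.234 to 0.330, so the trend is not the whole of it. A stronger drug response of that culture cannot be told apart, because the difference still followed the AGS effect with a partial r of 0.29 across genes once level, length and GC content were removed. The spread lies between the 2 treated SNU-1 libraries, and leaving out either of them raised the number of AGS calls. Of the AGS genes called with all libraries 97.0% had a mean FPKM under 1 in both SNU-1 groups, against 11.9% of the genes tested. Each gene has a single estimate of spread over all 4 groups, so a gene near 0 in every SNU-1 library takes on little of that pair's spread. Which genes passed in AGS was therefore shaped by their level in SNU-1. In a fit of AGS alone limma called 225 genes higher and 208 lower, against 29 and 4 with all 8 libraries. How the spread divides over the genes that SNU-1 expresses was not measured.

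Short non-coding genes made up 8 of the 10 SNU-1 calls. They rest on a median of 2.49 fragments per control library in the 7 with an annotated length, so the calls may come from chance zeros among many such genes, in a model that does not know how few fragments there are. Copies such as RNU7-151P (1.08 and 1.23 FPKM in SNU-1 controls) and RNU6-647P are also 0 in every AGS library. They passed the filter only through the SNU-1 controls, so they could only appear to fall. A drop of these RNAs under palbociclib stays open as an untested biological explanation, as does a change of their yield. How far the mRNA-seq kit captures such short RNAs is not given, so these values cannot speak for their abundance. Fragments on short non-coding genes per 1000000 were 205 and 173 in SNU-1 controls and 120 and 71.3 in treated libraries, and 150 and 123 against 96.5 and 97.5 in AGS.

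The interferon response list differed between the lines, and 12 of its 26 tested members had a mean FPKM under 1 in both SNU-1 groups. The 14 members expressed in SNU-1 had a median difference of 0.26 relative to all genes with all 8 libraries, close to the 0.29 of the other 12. A gap of 0.22 against 0.58 appeared only without SNU-1 palbociclib replicate 2. The median of all genes subtracted here was 0.29 with all 8 libraries and 0.034 without that library. As fitted, the 12 members hardly moved between the fits, and the gap came from a smaller difference of the 14 expressed members. Genes silent in SNU-1 and a weaker response of SNU-1 cannot be told apart as explanations, since for the expressed members the value without that library lies between what the 2 would give. Those 14 members had a relative median of 0.52 in AGS, and in SNU-1 one of 0.097 with all 8 libraries and 0.40 without that library, where 9 of them had a positive difference between the lines.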

How the results depend on the processing

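The fits of protein-coding genes, of the 12435 genes with a known GC content with the GC trend removed or left in, and without both treated SNU-1 libraries, and the subtraction of the median of all genes from list values, were chosen after the data were seen. Of the recomputed counts and correlations 121 stayed within 1.5 times, or for the correlation within its spread, and 107 moved. List values kept direction and side of the threshold 593 times, lost the call 117 times and reversed 10 times, and named genes kept theirs 398 times and lost the call 199 times with 0 reversals. Depth, at 15300000 to 19600000 fragments per library, limits what can be said of weakly expressed and very short genes.

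For AGS the counts higher and lower were 1 and 2 with a pseudocount of 0.1, 58 and 30 with no filter, 14 and 2 with the filter at FPKM 5, 3 and 2 in TPM, 225 and 208 in AGS alone, 2 and 0 without the trend, 4 and 0 with the GC trend removed, and 608 and 632 without both treated SNU-1 libraries. For SNU-1 they were 1 and 14 with a pseudocount of 0.1, 9 and 57 with no filter, 0 and 0 at FPKM 5, 1 and 3 with size factors, 0 and 10 in TPM, 17 and 91 after quantile normalization, 0 and 0 in SNU-1 alone and without the trend, 1 and 0 among protein-coding genes, and 80 and 248 with the GC trend removed. The difference between the lines had 26 and 9 with no filter and 1 and 0 at FPKM 5. Genes lower in both lines numbered 2 with no filter and 0 at FPKM 5, in each line alone, without the trend, among protein-coding genes and among genes with a known GC content, with the GC trend removed or left in. The only gene lower in both lines with all genes, SNORD58, is not among the genes tested at FPKM 5, the protein-coding genes or those with a known GC content, so its loss there follows from leaving it out. With the GC trend left in, those genes gave 28 and 3 in AGS and 1 and 7 in SNU-1, so the other changes with the GC trend removed do not come from the choice of genes. The control contrast gave 1112 and 874 at FPKM 5, 2414 and 2963 with the GC trend removed, and 3157 and 4212 without both treated SNU-1 libraries. The correlation between the lines was 0.60 with a pseudocount of 0.1 and 0.52 with the GC trend removed. In the fit of all 8 libraries a minimum fold of 2 kept every count of calls within 1.5 times. It left 28 and 4 of the AGS calls with no filter, and 118 of the 615 and 199 of the 636 AGS calls made without SNU-1 palbociclib replicate 2. The loss of the 8 non-coding SNU-1 calls among protein-coding genes and at FPKM 5 follows from leaving those genes out. TMSB15A was tested in both of these fits and lost its call in both. The cause of the other changes was not tested.

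With 1 library left out in turn, AGS calls ranged from 0 to 629 higher and 0 to 636 lower, SNU-1 calls from 0 to 2716 and 0 to 6051, and the difference from 0 to 5409 and 0 to 1532. The control contrast ranged from 1291 to 3155 higher and 999 to 4216 lower, genes shared up from 0 to 326 and shared down from 0 to 548, and the correlation from 0.54 to 0.71. The upper ends of the counts came without a treated SNU-1 library, while the correlation was lowest without SNU-1 palbociclib replicate 2 and highest without AGS palbociclib replicate 1. By construction leaving out a treated library leaves the group no spread of its own and the remaining library is assumed to vary like the other groups.

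Replicate numbers are shared between groups, but with 2 pairs per line they do not establish pairs. Deviations of equal numbers correlated at 0.009 in AGS and 0.571 in SNU-1. In SNU-1, replicate 2 differed from replicate 1 along GC content in the same direction in both groups. From the lowest to the highest GC bin the median difference ran from -0.48 to 0.18 in controls and from -1.40 to 0.75 in treated libraries. A factor shared by equal numbers in SNU-1 was not tested and cannot be set aside. With a replicate block, limma called 0 and 0 genes in AGS, 0 and 0 in SNU-1 (1204 and 4235 at an unadjusted p under 0.05), 0 in the difference and 0 lower in both lines, and 1860 and 1904 between controls, where the block uses up 2 of the 4 residual degrees of freedom.

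Reversed list values in the difference between the lines were 0.20 for ERK feedback genes after quantile normalization and 0.022 for immediate early genes with the GC trend removed. Mitochondrially encoded genes reversed to -0.033 with a pseudocount of 0.1, -0.049 with size factors and -0.11 with the GC trend removed, and in AGS to -0.014 after quantile normalization. With 1 library left out the difference ranged from -0.85 to 0.060 for cholesterol synthesis, -1.07 to 0.032 for oxidative phosphorylation and -1.04 to 0.026 for glycolysis, each reversed without SNU-1 palbociclib replicate 2, and from -1.50 to 0.068 for the ATF4 response, reversed without AGS control replicate 2. The cause was not tested.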

Other observations

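The histone test and the genes singled out here were chosen after their values were seen.

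In these mRNA-seq libraries genes of replication-dependent histones had higher values in treated AGS cells, while the DNA replication list was lower. How much of the histone RNA the kit captured is not given, so the values cannot speak for total histone RNA. Of 67 such genes 16 passed the filter, 14 of them with a positive fold change in AGS. Their relative median was 0.93 (limma camera p = 4.70e-13; p = 0.00171 with an estimated correlation). Some, such as H2BC11, H3C10 and H4C8 (0.31 and 0.24 FPKM in AGS controls, 1.53 and 1.39 treated), passed the filter only through the treated AGS libraries. Such genes could only appear to rise, so the positive share, the median and these p-values are partly set by the filter. H2BC12 was 24.0 and 18.5 FPKM in the AGS controls and 61.7 and 58.3 FPKM after palbociclib, and H2AC6 went from 4.35 and 4.74 to 19.5 and 16.5 FPKM. No histone gene passed on its own in the fit of all 8 libraries, and 6 rose without SNU-1 palbociclib replicate 2 (H2BC5, H4C8, H2AC6, H2BC4, H2BC21 and H2BC12). In SNU-1 the relative median was 0.26 (p = 0.0722; p = 0.137 with an estimated correlation), and the difference between the lines was 0.47 (p = 4.93e-06; p = 0.00919 with an estimated correlation). Without SNU-1 palbociclib replicate 2 these medians were 0.055 and 0.73, so both depend on that library. The cause was not tested. Genes of the highest GC bin shifted by 0.17 and 0.25 in the AGS libraries, less than the histone median.

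Among the AGS calls outside the named genes were the interferon-induced chemokines CXCL9 (2.03) and CXCL11 (1.96), CCL4L2, a chemokine gene with near-identical copies (1.98), the type III interferon IFNL3 (1.28) and the RNA helicase DHX58 (1.41). The others included SPRR2D, a cornified envelope gene like SPRR1A (1.44), and the kallikrein peptidases KLK14 (1.80) and KLK5 (0.91). Each had a limma adjusted p between 0.0155 and 0.0471 with all 8 libraries.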
